A study of Mus musculus with 12 samples.

How the data were processed

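The data were RNA sequencing counts from 12 libraries of mouse intestinal epithelial cells, 3 for each of 4 populations sorted by Sox9-GFP. Per the labels, each library came from total RNA of 12000 cells, depleted of ribosomal RNA, made with the Clontech SMARTer Total RNA Pico v2 kit and sequenced single-end. The authors deposited 1 table with a single value per gene symbol and library, taken here as a signal of unknown scale until checked. In every library 100% of the values were whole multiples of a single step (tolerance 0.01), which makes the values read counts divided by a size factor. The deposited values are not log2 values, and log2 fold changes and p-values of the authors were not used here. The aligner, counting program, genome build, annotation and the program behind the size factors are not given in the sources used here.

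The table held 30265 gene symbols, of which 30146 matched the reference annotation and 2416 were 0 in all libraries. Counts were recovered by dividing by the step, and the totals lay between 11.6 M and 17.0 M reads. A floor of 3 counts corresponds to between 2.38 and 4.61 normalised units, depending on the library. No library was left out, and the group of each came from its label. The pairing of replicate letters was checked on deviations from the population means: same-letter pairs correlated at 0.0521 to 0.341 (mean 0.156, 18 pairs) and pairs of different letters at a mean of -0.0781. Deviations within a population cancel out, so the mean of the different-letter pairs is largely set by that of the same-letter pairs. As the labels do not say what the letters stand for, the reported tests left them out and tests with the letter as a block were run beside them.

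Deposited values were used as log2(value + 1), and genes were kept with a value of at least 10 in at least 3 libraries, which left 16577. Differences were tested with limma (trend, moderated t and F statistics, 1 fit of all 12 libraries, prior degrees of freedom 4.10) with Benjamini-Hochberg adjustment within each comparison and a threshold of adjusted p below 0.05. A gene was enriched in a population when it passed in that direction against each of the other 3. Intervals for ratios of counts are 95% counting intervals, and a fold against a population without reads is given against the floor of 3 counts. Gene lists were tested with camera at a correlation between genes of 0.01, adjusted over the lists of each comparison. With a correlation estimated from the data, which with 3 replicates is itself uncertain, none of the 228 list tests was called, against 123 at 0.01.

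The choice of test, filter, threshold, gene lists, rule for named genes and alternatives was made before the data were examined, from the labels alone. By that rule, each comparison against Low and that of High with Negative names the 10 largest rises and 10 largest falls among genes with an adjusted p below 0.05, a mean of at least 100 over the 12 libraries and no overlap between the libraries of both populations. The other comparisons and the enriched sets name the 5 largest. Not every gene that met the rule is given in the text. Predicted genes, RIKEN clones, unnamed identifiers and ribosomal, small nuclear and small nucleolar RNAs are skipped. Sox9 is always given, and members of the fixed gene lists may be named where a list is described. Those members were chosen after their values were seen, mostly among members whose call held in every alternative.

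The 38 gene lists cover intestinal cell types (active and reserve stem, enteroendocrine transcription factors, hormones and granule, tuft, goblet, Paneth), absorptive programmes (brush border enzymes and cytoskeleton, lipid absorption, fatty acid oxidation, cholesterol synthesis, villus tip, antimicrobial genes), transcription factors and signalling (Wnt, Notch, BMP), cell cycle, histones, chromatin, ribosomal and mitochondrial genes, and cells other than epithelium. They were written from general knowledge of marker genes, and members below the filter were left out of counts of measured genes.

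The alternatives were the replicate letter as a block, a pseudocount of 0.5 or 5, no filter, a mean of at least 50, scaling to the same total, quantile scaling, recomputed median-of-ratios scaling, robust empirical Bayes, library weights, edgeR (quasi-likelihood, TMM), DESeq2, a 2-fold minimum, a fit of the 6 libraries of a comparison alone, and leaving out each library in turn. Lists were also tested with an estimated correlation and with fry. A fit without the Sublow libraries was chosen after the data were seen. On the recovered counts, the count tests called 7357 (edgeR) and 7714 (DESeq2) genes for High against Low, 4169 and 4755 for Sublow against Low, 9460 and 9677 for Negative against Low, 9066 and 9300 for High against Negative, 3995 and 5372 for Sublow against Negative, and 8770 and 9067 for High against Sublow.

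The tests were tested on simulated counts with the depths of the real libraries and a single spread per gene, shared by all populations. The simulated genes were independent, had no replicate effect, and few of them were changed. The real libraries differed in these respects, with a wider spread in Sublow, so the rates below may not carry over to them. Of 100 genes changed 4-fold, limma recovered between 83 and 90 in each comparison. Of 100 changed 2-fold it recovered 54 (High against Low), 39 (Sublow against Low), 33 (Negative against Low), 35 (High against Negative), 38 (Sublow against Negative) and 45 (High against Sublow). None was called in the wrong direction, and of 16377 genes simulated without a change, counted before the filter, between 1 and 14 were called. After the filter between 16218 and 16237 genes, changed ones included, were tested. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Transcript isoforms, alignment and the chromatin data named in the series title were not analysed here.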

Results

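Gene expression was measured by RNA sequencing in mouse (C57Bl/6) intestinal epithelial cells that carried a Sox9-GFP reporter and had been sorted by flow cytometry into 4 populations: Sox9 High, Sox9 Low, Sox9 Sublow and Sox9 Negative. Sox9 is a transcription factor of the intestinal crypt, and the reporter lets cells be separated by how much of it they express. In published work with this reporter, Low has been described as rich in cycling stem cells, Sublow in progenitors, High in enteroendocrine and tuft cells, and Negative in differentiated cells. Each population had 3 libraries (replicates A, B and C), each made from total RNA of 12000 cells after removal of ribosomal RNA. The libraries held between 11.6 M and 17.0 M reads assigned to genes (M, 1e6), with means of 15.0 M in High, 14.2 M in Low, 15.4 M in Sublow and 15.3 M in Negative. Values below are normalised read counts given as mean ± SD (n = 3 libraries per population), and log2 differences are given with their standard error. That error comes from the fit of all 12 libraries, which pools the spread of a gene over the 4 populations. It is therefore not the spread of the populations compared. The Sublow libraries varied most, so standard errors and p-values can be too small where Sublow takes part. Fold changes are on the log2(value + 1) scale and average the logs of the libraries. They understate changes of genes with few reads in every library, and can overstate them where a single library holds most of a population's reads. The fold from summed reads, adjusted for depth, is given where it differs most. Nothing in the labels says that the replicates came from separate animals, so p-values measure the spread between samples only. Intervals and floors cover counting error only. Values of multi-copy families (Defa genes, histones and ribosomal proteins) are uncertain because reads of near-identical genes cannot be placed with certainty.

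Sox9 itself was highest in High and fell in the order of the sort gates. It measured 20262 ± 1220.2 in High, 6601 ± 921 in Low, 2084 ± 897 in Sublow and 604 ± 191 in Negative. High was 3.08-fold above Low (log2 difference 1.62 ± 0.30, adjusted p = 0.000874), and Low was 3.35-fold above Sublow (adjusted p = 0.00173). Sublow was 3.37-fold above Negative (adjusted p = 0.00335), and the widest step, High over Negative, was 34.8-fold (adjusted p = 3.7e-08). Within each of these comparisons, all 3 libraries of the higher gate lay above all 3 of the lower gate.

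**Figure D1:**
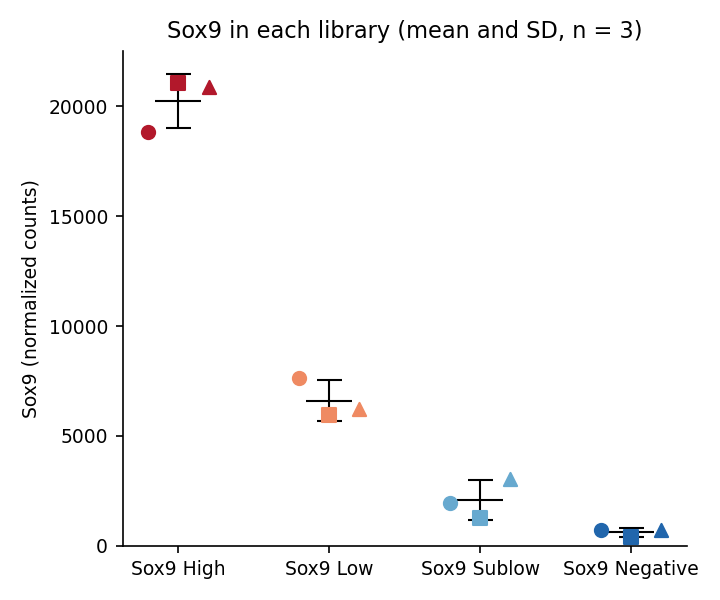
Sox9 in normalised counts for each of the 12 libraries by population (circle, replicate A; square, B; triangle, C), with the mean and SD as bars. The means descend from 20262 in High to 604 in Negative.

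Along the 1st principal component the libraries lay in the order High, Low, Sublow and Negative without overlap. Those of Sublow lay farthest from each other. On the 1st and 2nd components Sublow B (-86.9, 1.97) lay nearer to Negative A (-104.5, 32.7) than to Sublow A (-58.3, -27.5) or Sublow C (-42.6, -81.4). The 1st principal component held 60.3% of the variance and the 2nd 20.3%. Correlations of log2 values within a population ran from 0.941 to 0.965 in Sublow and from 0.964 to 0.974 in the other populations. The share of reads from the mitochondrial genome was 1.47% ± 0.126 in High, 2.89% ± 0.394 in Low, 3.51% ± 0.44 in Sublow and 4.55% ± 0.471 in Negative. Of 16577 genes with enough reads to test, 11521 (69.5%) differed somewhere among the 4 populations by limma's moderated F-test. In 12 of 12 libraries, the deviation from the population mean correlated best with libraries of the same replicate letter, so counts with the letter as a block are given beside each comparison.

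**Figure D2:**
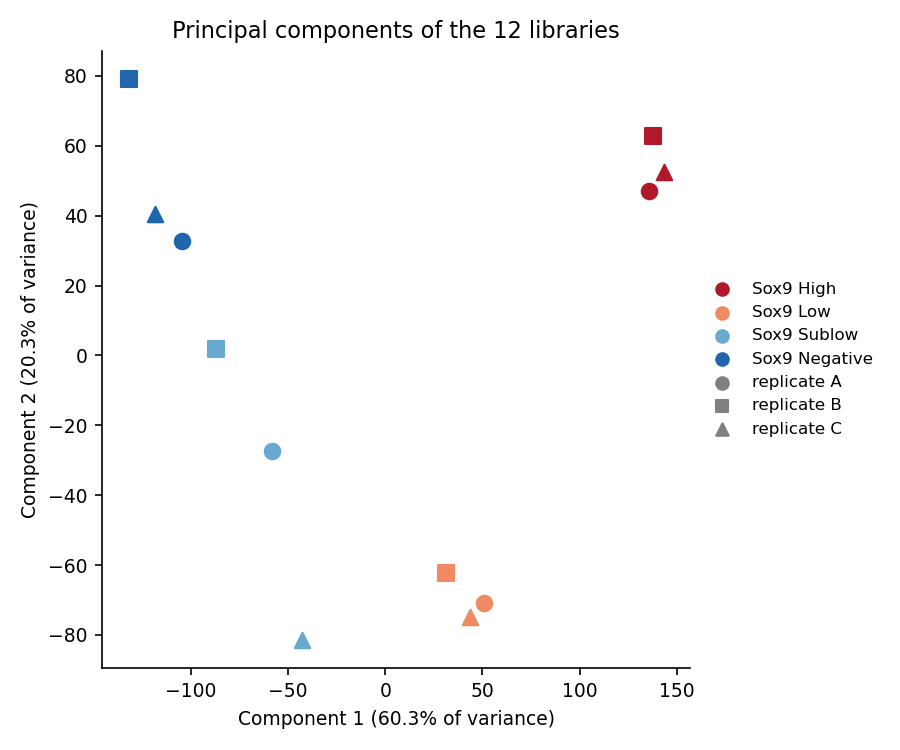
The 12 libraries on the 1st and 2nd principal components of log2(value + 1), coloured by population and shaped by replicate. Component 1 (60.3% of the variance) orders the populations without overlap, and component 2 held 20.3%. The Sublow libraries lie farthest from each other, and Sublow B lies nearer to Negative A than to the other Sublow libraries.

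The comparison of Sox9 High with Sox9 Low asked which genes set apart the cells with the most reporter from those of the stem cell gate. Enteroendocrine and tuft cell genes were far higher in High, and stem cell, cell cycle and goblet cell genes were lower. Chga, a granin packed with hormones into secretory granules, measured 116336 ± 30447 in High and 11576 ± 4073 in Low (log2 difference 3.36 ± 0.39 (SE), adjusted p = 4e-05). Dclk1, a kinase used as a tuft cell marker, measured 39366 ± 1548 against 4934 ± 1379 (log2 difference 3.03 ± 0.41 (SE), adjusted p = 0.000122). Lgr5, the R-spondin receptor that marks crypt base stem cells, went the other way, at 759.9 ± 162 against 2476 ± 769 (log2 difference -1.68 ± 0.44 (SE), adjusted p = 0.00864).

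Of 18 genes of the enteroendocrine secretory granule, 17 rose (18 when adjusted over the list alone), with a median log2 difference of 2.83 (camera adjusted p = 3.72e-10, against adjusted p = 0.223 with an estimated correlation). They included the granins Chgb (2.90) and Scg2 (3.25), the prohormone convertase Pcsk1 (2.80) and the lectin Reg4 (4.19). Among 12 hormone genes 9 rose (10 adjusted over the list alone; camera adjusted p = 0.00207, against adjusted p = 0.381 with an estimated correlation), with secretin (Sct, 4.11), peptide YY (Pyy, 4.37), cholecystokinin (Cck, 3.61) and Tph1, the enzyme of serotonin synthesis (2.62). Of 15 enteroendocrine transcription factors 13 rose and 1 fell, the same numbers when adjusted over the list alone (camera adjusted p = 3.31e-05, against adjusted p = 0.381 with an estimated correlation). Neurod1 (2.72) and Pax6 (2.66) were among those that rose. The member that fell was Neurog3, the factor that starts the enteroendocrine fate, which measured 15.0 ± 9.42 in High and 122 ± 26.5 in Low (log2 difference -3.09 ± 1.11 (SE), adjusted p = 0.0405), a call lost without any 1 of High B, High C, the 3 Low libraries or Sublow A (adjusted p from 0.0536 to 0.127).

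The tuft cell list rose almost as a whole: 25 of 26 genes were higher in High, also when adjusted over the list alone, with a median of 3.10 (camera adjusted p = 2.08e-12, against adjusted p = 0.381 with an estimated correlation). Trpm5, the cation channel of taste signalling, measured 26730.4 ± 369 against 2876 ± 1035. The leukotriene and prostaglandin enzymes Alox5 (3.87) and Ptgs1 (4.00) and the cytokine Il25 (3.32) rose with it. Beside these, the pan-leukocyte phosphatase Ptprc measured 2469 ± 779 in High and 89.2 ± 26.8 in Low, and was the 1 of 11 T cell genes that rose (camera adjusted p = 0.381). Of 7 myeloid genes 1 rose and 3 fell (camera adjusted p = 0.433). Summed stromal and muscle markers measured 3775 ± 947 in High and 841 ± 350 in Low, most of it from Vim (3519 ± 925 against 625 ± 350.5, adjusted p = 0.173, but 0.0102 with edgeR, 0.0331 with a pseudocount of 5, 0.0344 with library weights and 0.0323 without Sublow replicate B). Summed enteric neuron and glia markers measured 1838 ± 163 against 556 ± 84.3, most of it from the receptor Ret, which rose by 2.47. The largest rises by rule were Sbpl (8.28), the protein kinase C gene Prkcb (6.31), alpha-fetoprotein (Afp, 6.12), the sialic acid-binding lectin Siglecf (5.96), Basp1 (5.93), Trim38 (5.80), the folate receptor Folr1 (5.79), the small GTPase Rac2 (5.68), pleckstrin (Plek, 5.64) and the axonemal dynein Dnah6 (5.55).

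Stem and cycling genes were lower in High. Of 24 active stem cell genes 19 fell and none rose (21 and 1 adjusted over the list alone), with a median of -1.95 (camera adjusted p = 1.47e-08, against adjusted p = 0.381 with an estimated correlation). Olfm4 fell by 4.16 on the log2 scale, the stem cell factor Ascl2 by 2.95 and Smoc2 by 2.25. All 24 S phase genes and all 24 mitotic genes fell (camera adjusted p = 6.86e-14 and 5.7e-17, against adjusted p = 0.381 for both with an estimated correlation). The counts were the same when adjusted over the list alone. Mki67, a marker of cycling cells, measured 1461 ± 563 in High against 20303 ± 1186 in Low. Of 16 Wnt targets 9 fell, among them Axin2 (-1.81) and Myc (-3.20), and 2 rose, Prox1 (2.22) and Wif1 (2.63; 10 and 3 adjusted over the list alone; camera adjusted p = 0.00927, against adjusted p = 0.381 with an estimated correlation). Of 13 Notch pathway genes 8 fell and 2 rose, also over the list alone, with Hes1, a target of Notch signalling, at -3.71 and Notch1 at -2.01 (camera adjusted p = 0.0017, against adjusted p = 0.381 with an estimated correlation). BMP pathway genes went the other way: 6 of 11 rose and 1 fell (7 and 1 adjusted over the list alone), with the pseudoreceptor Bambi at 2.20 and the target Id2 at 1.98 (camera adjusted p = 0.029, against adjusted p = 0.381 with an estimated correlation). The replication-dependent histones followed the cell cycle, 58 of 65 falling and 1 rising (59 and 1 adjusted over the list alone; camera adjusted p = 4.63e-20, against adjusted p = 0.381 with an estimated correlation), with Hist1h2ao the largest log2 fall by rule (-6.12, or 69.5-fold, but 17.2-fold from summed reads). It was at -3.55 without High replicate B and -7.59 without High replicate A.

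Goblet cell genes fell in 17 of 19 cases, the same when adjusted over the list alone, with a median of -3.30 (camera adjusted p = 6.19e-11, against adjusted p = 0.381 with an estimated correlation). The gel-forming mucin Muc2 measured 1702 ± 353 in High and 82498 ± 53807 in Low. Zg16 (-5.57), Clca1 (-5.46) and the calpain Capn9 (-4.51) were among the largest falls, as were Fer1l6 (-4.97), the chemokine Ccl6 (-4.80) and the tryptophan-degrading enzyme Ido1 (-4.74). Low replicate B stood apart, with 24605 of the 36171 Zg16 reads, 168880 of the 280807 Muc2 reads and 596 of the 758 Ido1 reads in Low. Without it the falls were smaller and still called, at -4.87 for Zg16, -4.94 for Muc2, -4.97 for Clca1, -4.08 for Capn9, -4.37 for Fer1l6 and -3.70 for Ido1. Of 18 Paneth cell genes 12 fell and 2 rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.00121, against adjusted p = 0.496 with an estimated correlation). Lysozyme (Lyz1) was at -4.06 and the defensins Defa23 and Defa34 at -4.65 (40.4 ± 37.3 in High against 465 ± 296 in Low) and -4.48, with Defa23 at -2.67 without High replicate B. The pair that rose was the Wnt ligand Wnt3 (1.89) and the receptor Kit (0.92), whose call was lost without High replicate C (adjusted p = 0.0524). Of the factors of secretory fate, 5 of 13 fell, with Atoh1 at -3.91, and 1, the tuft cell factor Gfi1b, rose (3.35; 6 and 2 adjusted over the list alone; camera adjusted p = 0.0634, and down to 0.0391 without High replicate B or Low replicate C).

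No list of enterocyte structure or absorption was called between these gates, although single genes differed. Of 21 brush border enzymes and transporters 3 rose and 3 fell, also over the list alone (camera adjusted p = 0.661). The brush border cytoskeleton had 7 of 14 genes higher in High, also over the list alone (camera adjusted p = 0.263), and its summed level was 102128 ± 4828 in High and 47725 ± 11873 in Low. Of 21 intestinal and absorptive transcription factors 5 fell and 1 rose (4 and 1 adjusted over the list alone). Their camera adjusted p was 0.0677, and 0.0336 when scaled to the same total, 0.0475 with the replicate block and 0.0315 without Low replicate C. By contrast, 6 of 8 antimicrobial genes fell, also over the list alone (camera adjusted p = 3.08e-05, against adjusted p = 0.381 with an estimated correlation), with the lectins Reg3b at -2.06 and Reg3g at -2.50. Of 18 cholesterol synthesis genes 11 rose (15 adjusted over the list alone; camera adjusted p = 4.96e-05, against adjusted p = 0.381 with an estimated correlation), with Hmgcs1 at 1.11 and Sqle at 1.27. In the limma test with Benjamini-Hochberg adjustment, 7110 genes differed between High and Low, 3915 higher and 3195 lower in High (8027 with the replicate letter as a block). At 2-fold or more, 2435 were higher and 1947 lower. In all, 10061 genes (60.7%) had no overlap between the 3 libraries of either population, where chance gives 10%.

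The comparison of Sox9 Sublow with Sox9 Low asked what differed between the gates described as progenitor and stem cell. Genes of the absorptive enterocyte were higher in Sublow, and stem cell, enteroendocrine and tuft cell genes were lower. No mitotic or S phase gene passed the test. Sucrase-isomaltase (Sis), a disaccharidase of the brush border, measured 51014 ± 34931 in Sublow and 6985 ± 3021 in Low (log2 difference 2.71 ± 0.44 (SE), adjusted p = 0.0014). Lgr5 measured 299.6 ± 204 against 2476 ± 769 (log2 difference -3.25 ± 0.44 (SE), adjusted p = 0.000574), and Dclk1 91.3 ± 58.7 against 4934 ± 1379 (log2 difference -5.92 ± 0.41 (SE), adjusted p = 8.31e-06).

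Of 21 brush border enzymes and transporters 19 rose (20 adjusted over the list alone), with a median of 2.52 (camera adjusted p = 3.71e-13, against adjusted p = 0.295 with an estimated correlation). They included lactase (Lct, 3.49), the aminopeptidase Anpep (3.28) and the glucose transporters Slc5a1 (2.47) and Slc2a2 (3.36). Of 21 lipid absorption genes 20 rose and 1 fell, also over the list alone (camera adjusted p = 1.62e-11, against adjusted p = 0.318 with an estimated correlation), with apolipoprotein A1 (Apoa1) at 3.52, the fatty acid-binding protein Fabp1 at 3.59 and the receptor Scarb1, the member that fell, at -1.09. In the brush border cytoskeleton 11 of 14 genes rose (12 adjusted over the list alone; camera adjusted p = 5.33e-08, against adjusted p = 0.32 with an estimated correlation), villin (Vil1) by 1.60. All 8 antimicrobial genes of the lower villus rose, also over the list alone (camera adjusted p = 2.13e-08, against adjusted p = 0.156 with an estimated correlation), with the lectin Reg3b at 12648 ± 2110.4 against 1991 ± 237. Of 21 intestinal and absorptive transcription factors 11 rose and none fell (15 and 1 adjusted over the list alone; camera adjusted p = 1.9e-06, against adjusted p = 0.156 with an estimated correlation), among them Hnf4g (2.18) and Maf (2.85). The largest rises by rule were Fam151a (4.38), Unc93a2 (4.01), the dicarboxylate transporter Slc13a2 (3.76), the trypsin inhibitor Spink1 (3.72), Slc5a4a (3.69), the dipeptidase Dpep1 (3.66), Ggt1 (3.62), Reg3a (3.60), Cyp2b10 (3.60) and Fabp1. Except for Fam151a (492 ± 72.8 in Sublow), these genes varied widely between the Sublow libraries. A single library held 18881 of the 30196 Fabp1 reads in Sublow, 2765 of 4155 for Cyp2b10 and 951 of 1372 for Slc5a4a. The summed brush border enzyme list measured 281428 ± 184965 in Sublow and 46544 ± 15727 in Low.

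Active stem cell genes fell in 19 of 24 cases (24 adjusted over the list alone; camera adjusted p = 3.52e-11, against adjusted p = 0.32 with an estimated correlation), with Tnfrsf19 at -3.60, Axin2 at -1.29 and Notch1 at -1.55. Of 16 Wnt targets 13 fell (14 adjusted over the list alone; camera adjusted p = 6.61e-08, against adjusted p = 0.156 with an estimated correlation), Nkd1 by 2.40 on the log2 scale. None of 24 mitotic genes passed the test, over all genes or over the list alone (median -0.33, camera adjusted p = 0.122; 0.0107 with quantile scaling, and down to 0.0375 without Sublow replicate C or Negative replicate B), nor did any of 24 S phase genes or 65 replication-dependent histones by limma. Mki67 measured 16042 ± 3698 in Sublow and 20303 ± 1186 in Low. As a set the S phase genes had a camera adjusted p of 0.0467 (adjusted p = 0.774 with an estimated correlation), a call that leaving out any 1 of Low A, Low C, Sublow A, Sublow B or Negative C ended (up to adjusted p = 0.516).

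Enteroendocrine and tuft cell genes were lower in Sublow. Of 18 granule genes 17 fell (camera adjusted p = 5.25e-16, against adjusted p = 0.0517 with an estimated correlation), of 12 hormone genes 11 (camera adjusted p = 2.4e-08, against adjusted p = 0.156 with an estimated correlation) and of 15 enteroendocrine transcription factors 14 (camera adjusted p = 1.62e-11, against adjusted p = 0.156 with an estimated correlation), with the same numbers over each list alone. Neurotensin (Nts) fell most (-7.06, or 133-fold, but 51.5-fold from summed reads), and Chga was at -3.94. Of 26 tuft cell genes 24 fell, also over the list alone (camera adjusted p = 8.5e-24, against adjusted p = 0.0823 with an estimated correlation), with Rgs13 at -6.50, Sh2d6 at -5.54 and Trpm5 at -4.49. Other large falls were Dgki (-5.85), Pygl (-5.67), Pyy (-5.72) and Ccdc129 (-5.31). The protocadherin Pcdh20 measured 55.2 ± 19.7 in Low and had no read in Sublow, which made it at least 54.3-fold lower against a floor of 3 counts over the population. Goblet cell genes had a median of 0.91, but 2 of 19 passed the test, also over the list alone (camera adjusted p = 0.000281, against adjusted p = 0.476 with an estimated correlation). They were the membrane mucin Muc13 (1.03) and guanylin (Guca2a, 1.09), whose call was lost without Low replicate A (adjusted p = 0.078) or C (adjusted p = 0.0835). Muc2 measured 141009 ± 29689 against 82498 ± 53807 (adjusted p = 0.0974, and 0.00698 without Low replicate B). Of 18 Paneth cell genes 3 fell, also over the list alone (camera adjusted p = 0.0198, against adjusted p = 0.633 with an estimated correlation), and this call was lost without Low replicate C (adjusted p = 0.0663).

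In all, 3979 genes differed between Sublow and Low by limma with Benjamini-Hochberg adjustment, 2201 higher and 1778 lower in Sublow (5002 with the replicate letter as a block). At 2-fold or more, 965 were higher and 1211 lower, and 6127 genes (37.0%) had no overlap between the 3 libraries of either population, where chance gives 10%. The count was 2500 without Sublow replicate B, 2521 without Low replicate A, 2473 in a fit of these 6 libraries alone and 7880 with library weights. With all libraries scaled to the same total, which put the median gene at a log2 difference of -0.33, 28.5% of called genes were higher in Sublow, against 55.3% with the deposited scaling.

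The comparison of Sox9 Negative with Sox9 Low asked how cells without the reporter differed from those of the stem cell gate. Enterocyte genes were higher, and stem cell, cell cycle, enteroendocrine and tuft cell genes were lower. Lactase (Lct) measured 56355 ± 15412 in Negative and 1252 ± 953 in Low (log2 difference 5.71 ± 0.79 (SE), adjusted p = 7.59e-05). Lgr5 measured 67.2 ± 22.9 against 2476 ± 769 (log2 difference -5.19 ± 0.44 (SE), adjusted p = 4.95e-06), and Chgb, a granin, 351 ± 292 against 39154 ± 13668 (log2 difference -7.40 ± 0.80 (SE), adjusted p = 1.54e-05).

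All 21 brush border enzymes and transporters rose, also when adjusted over the list alone, with a median of 4.24 (camera adjusted p = 7.11e-11, against adjusted p = 0.338 with an estimated correlation). Sis rose by 4.44, the alkaline phosphatase Alpi by 4.71 and the peptide transporter Slc15a1 by 4.14. Of 21 lipid absorption genes 20 rose and none fell (20 and 1 adjusted over the list alone; camera adjusted p = 7.95e-10, against adjusted p = 0.338 with an estimated correlation), including Apoa4 (5.33), Mttp, which loads lipid onto apolipoprotein B (4.53), and Fabp1 (5.60). All 14 brush border cytoskeleton genes rose, also over the list alone (camera adjusted p = 1.23e-07, against adjusted p = 0.338 with an estimated correlation), with Vil1 at 2.83 and keratin 20 (Krt20) at 3.20. Fatty acid oxidation genes rose in 12 of 15 cases and fell in 1, also over the list alone (camera adjusted p = 2.8e-05, against adjusted p = 0.338 with an estimated correlation), with Acadm at 1.80. All 8 antimicrobial genes rose, also over the list alone (camera adjusted p = 3.16e-06, against adjusted p = 0.285 with an estimated correlation), Reg1 by 4.54. Of 21 intestinal and absorptive transcription factors 17 rose and 2 fell (19 and 2 adjusted over the list alone; camera adjusted p = 2.14e-05, against adjusted p = 0.285 with an estimated correlation), with Maf at 4.38, Hnf4g at 3.48, Creb3l3 at 4.77 and, of those that fell, Cdx1 at -0.67. The largest rises by rule also held Unc93a2 (6.20), Cyp2b10 (5.92), the sugar transporters Slc2a7 (5.90), Slc5a4a (5.73), Slc2a2 (5.45) and Slc5a11 (5.41), and Reg3a (5.43) and Ggt1 (5.42).

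All 24 active stem cell genes fell, also over the list alone (camera adjusted p = 4.33e-11, against adjusted p = 0.338 with an estimated correlation), with Olfm4 at -5.90 (59.6-fold, and 31.1-fold from summed reads), Ascl2 at -6.05 and the hyaluronan receptor Cd44 at -5.17. Of 16 Wnt targets 14 fell, also over the list alone (camera adjusted p = 2.82e-06, against adjusted p = 0.285 with an estimated correlation), and of 13 Notch pathway genes 9, again the same over the list alone (camera adjusted p = 0.00292, against adjusted p = 0.347 with an estimated correlation). All 24 mitotic genes fell (camera adjusted p = 1.11e-08, against adjusted p = 0.353 with an estimated correlation), and of 24 S phase genes 23 fell and 1 rose (camera adjusted p = 1.04e-06, against adjusted p = 0.353 with an estimated correlation), with the same counts over each list alone. Mki67 measured 3794 ± 2282 against 20303 ± 1186. Replication-dependent histones fell in 58 of 65 cases, also over the list alone (camera adjusted p = 4.33e-11, against adjusted p = 0.353 with an estimated correlation).

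Every one of 15 enteroendocrine transcription factors fell (camera adjusted p = 1.54e-08, against adjusted p = 0.294 with an estimated correlation), as did 11 of 12 hormones (camera adjusted p = 2.45e-06, against adjusted p = 0.285 with an estimated correlation) and 17 of 18 granule genes (camera adjusted p = 7.13e-10, against adjusted p = 0.237 with an estimated correlation). Of 26 tuft cell genes 23 fell (camera adjusted p = 6.64e-12, against adjusted p = 0.285 with an estimated correlation), and these 4 counts were the same over each list alone. Glucagon (Gcg) was at -8.59 (387-fold, but 135-fold from summed reads, 95% counting interval 93.7 to 201) and Gip at -8.35 (327-fold on this scale, with 185 ± 243 in Negative against 20442 ± 3840.4 in Low). Both depended on the Negative libraries, with Gcg at -10.06 without replicate A and -7.59 without B, and Gip at -9.80 and -6.62. Further falls were the calcium sensor Scgn (-7.15) and the tuft genes Sh2d7 (-8.73) and Rgs13 (-7.30). Pygl (-7.39), Kctd12 (-7.17), Amigo2 (-7.11) and Nts (-10.78) completed the largest falls by rule. Of 19 goblet cell genes 15 fell and 1 rose, also over the list alone (camera adjusted p = 0.00351, against adjusted p = 0.519 with an estimated correlation), with Muc2 at -1.75. The member that rose was Muc13 (1.68), a membrane mucin that enterocytes also carry. Of 13 factors of secretory fate 9 fell and 2 rose, also over the list alone (camera adjusted p = 0.00508, against adjusted p = 0.353 with an estimated correlation), with Atoh1 at -1.67 and Sox4 at -4.36. Paneth cell genes were split: 2 of 18 rose and 3 fell (1 and 2 adjusted over the list alone; median 1.20, mean 0.52, camera adjusted p = 0.52). Summed over the list, they measured 103480 ± 45849 in Negative and 36545 ± 15741 in Low, with Lyz1 at 25783 ± 11313 against 9174 ± 4633 (adjusted p = 0.109, and 0.00708 without High replicate B). Kit (-2.80) was among those that fell.

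By limma with Benjamini-Hochberg adjustment, 9474 genes differed between Negative and Low, 4446 higher and 5028 lower in Negative (10006 with the replicate letter as a block). At 2-fold or more, 2550 were higher and 3580 lower, and 11029 genes (66.5%) had no overlap between the 3 libraries of either population, where chance gives 10%. With all libraries scaled to the same total, which put the median gene at a log2 difference of -0.60, 23.2% of called genes were higher in Negative, against 46.9% with the deposited scaling.

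**Figure D3:**
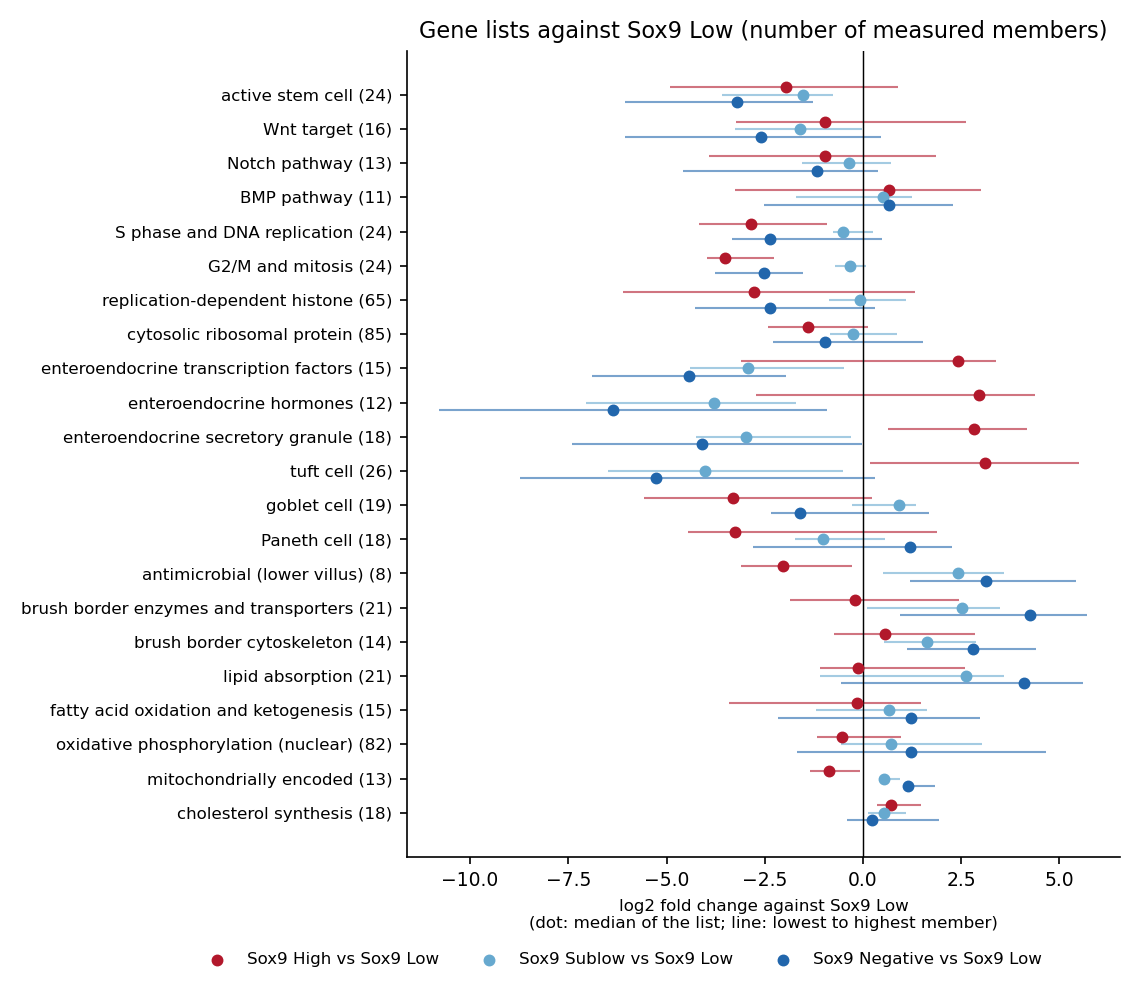
Log2 fold change against Sox9 Low of 22 gene lists (dot, median of the measured members; line, lowest to highest member) for High, Sublow and Negative. The tuft cell list has a median of 3.10 in High and -5.27 in Negative, and the brush border enzyme list medians of 2.52 in Sublow and 4.24 in Negative; these signs held under each scaling tried.

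The comparison of Sox9 High with Sox9 Negative set the ends of the reporter's range against each other. The largest fold changes of any pair of populations were here, in hormone and tuft cell genes, and enterocyte genes went the other way. Nts, a gut peptide, measured 54832 ± 16182 in High and 2.17 ± 1.88 in Negative (log2 difference 14.31 ± 1.28 (SE), adjusted p = 1.29e-06). Dclk1 measured 39366 ± 1548 against 44.1 ± 19.1 (log2 difference 9.85 ± 0.41 (SE), adjusted p = 3.99e-09), and Apoa1 2089.6 ± 1092 against 93697 ± 27640.4 (log2 difference -5.59 ± 0.70 (SE), adjusted p = 2.28e-05).

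All 26 tuft cell genes were higher in High, also over the list alone, with a median of 8.49 (camera adjusted p = 6.07e-17, against adjusted p = 0.204 with an estimated correlation). Of 18 granule genes 17 were higher (18 over the list alone; camera adjusted p = 8.88e-13, against adjusted p = 0.103 with an estimated correlation), of 12 hormones 11 (12 over the list alone; camera adjusted p = 3.13e-07, against adjusted p = 0.242 with an estimated correlation) and of 15 enteroendocrine transcription factors 14, also over the list alone (camera adjusted p = 3.24e-09, against adjusted p = 0.276 with an estimated correlation). Sh2d7 (11.88), Gcg (11.86), Gip (10.95), Sh2d6 (10.85), Afp (10.78), Amigo2 (10.49) and Siglecf (10.42) were among the largest rises. From summed reads Gcg was 1276-fold higher (95% counting interval 888 to 1906), against 3715-fold on the log2 scale, and Gip 587-fold, against 1985-fold. Their log2 differences were 10.85 and 9.22 without Negative replicate B, and 13.32 and 12.41 without A. Pyy had 2 reads in all of Negative, and its ratio was 5371 (95% counting interval 1487 to 44353). Active stem cell genes were higher in High in 14 of 24 cases and lower in 1, also over the list alone (camera adjusted p = 0.00533, against adjusted p = 0.777 with an estimated correlation), with the RNA-binding protein Msi1 at 5.58 and Cd44 at 5.42.

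Brush border enzymes and transporters were lower in High in 20 of 21 cases, also over the list alone (camera adjusted p = 1.91e-09, against adjusted p = 0.537 with an estimated correlation), with Lct at -5.99 and Slc2a2 at -6.43. Of 21 lipid absorption genes 20 were lower and 1, Scarb1 (2.92), was higher, also over the list alone (camera adjusted p = 2.17e-08, against adjusted p = 0.537 with an estimated correlation). All 8 antimicrobial genes were lower, also over the list alone (camera adjusted p = 2.12e-07, against adjusted p = 0.213 with an estimated correlation), Reg1 at -6.52 and Reg3a at -6.58. Of 18 Paneth cell genes 14 were lower and 2 higher, also over the list alone (camera adjusted p = 0.00416, against adjusted p = 0.593 with an estimated correlation; adjusted p = 0.0534 with DESeq2), with Lyz1 at -5.56. Other large falls were Preb (-7.55), Defa23 (-6.89, or 119-fold, but 48.2-fold from summed reads), the glutathione S-transferase Gsta1 (-6.66), Fam151a (-6.54), Slc2a7 (-6.37), the glucuronosyltransferase Ugt2b5 (-6.36) and Slc5a4a (-6.32). Preb had an SE of 2.11 and 5 reads in High, all in a single library. From summed reads its fold was 261 (95% counting interval 111 to 806), against 188 on the log2 scale. Of 24 mitotic genes 11 were lower in High (10 over the list alone; camera adjusted p = 0.00533, against adjusted p = 0.805 with an estimated correlation), a call that was lost without Negative replicate A (adjusted p = 0.0651). Goblet cell genes were lower in 13 of 19 cases and higher in 1, also over the list alone (camera adjusted p = 0.000347, against adjusted p = 0.579 with an estimated correlation), with Muc2 at -3.69.

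In total, 9054 genes differed between High and Negative by limma with Benjamini-Hochberg adjustment, 4776 higher and 4278 lower in High (9701 with the replicate letter as a block). At 2-fold or more, 3536 were higher and 2704 lower, and 10753 genes (64.9%) had no overlap between the 3 libraries of either population, where chance gives 10%. Scaling to the same total moved the median gene to a log2 difference of 0.50 and 74.2% of called genes were then higher in High, against 52.8%.

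The comparison of Sox9 Sublow with Sox9 Negative asked how the pair of gates with the least reporter differed. Cell cycle and goblet cell genes were higher in Sublow, and enterocyte and Paneth cell genes were higher in Negative. These calls come from the fit of all 12 libraries. A fit of the 6 Sublow and Negative libraries alone called 41 genes higher and 5 lower in Sublow. Most calls of single genes given below for this comparison, in either direction, therefore depend on the larger fit. Mki67 measured 16042 ± 3698 in Sublow and 3794 ± 2282 in Negative (log2 difference 2.26 ± 0.40 (SE), adjusted p = 0.00419). Muc2 measured 141009 ± 29689 against 22428 ± 7226 (log2 difference 2.69 ± 0.38 (SE), adjusted p = 0.00167).

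All 24 mitotic genes were higher in Sublow, also over the list alone (camera adjusted p = 3.86e-15, against adjusted p = 0.349 with an estimated correlation), with Top2a at 2.48. Of 24 S phase genes 20 were higher (21 over the list alone; camera adjusted p = 1.79e-10, against adjusted p = 0.349 with an estimated correlation), the helicase subunit Mcm2 by 2.57. Of 65 replication-dependent histones 56 were higher (59 over the list alone; camera adjusted p = 3.83e-23, against adjusted p = 0.349 with an estimated correlation). Goblet cell genes were higher in 17 of 19 cases, with 17 higher and 1 lower over the list alone and a median of 2.50 (camera adjusted p = 1.7e-10, against adjusted p = 0.349 with an estimated correlation). Fcgbp, a mucus component, was at 2.56, the trefoil peptide Tff3 at 2.56 and Clca1 at 2.69. The factors of secretory fate were higher in 9 of 13 cases (10 over the list alone; camera adjusted p = 1.41e-05, against adjusted p = 0.349 with an estimated correlation), Atoh1 by 2.39 and Spdef by 2.50. Active stem cell genes were higher in 20 of 24 cases (23 over the list alone; camera adjusted p = 1.96e-11, against adjusted p = 0.349 with an estimated correlation), with Olfm4 at 3.64 and Lgr5 at 1.94. Granule genes were higher in 11 of 18 cases (12 over the list alone; camera adjusted p = 1.93e-05, against adjusted p = 0.349 with an estimated correlation), Chgb by 3.66, and Gip was at 4.64.

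Enterocyte genes were lower in Sublow. Of 21 brush border enzymes and transporters 15 were lower (20 over the list alone; camera adjusted p = 1.12e-07, against adjusted p = 0.355 with an estimated correlation), and of 21 lipid absorption genes 17 (21 over the list alone; camera adjusted p = 1.1e-07, against adjusted p = 0.353 with an estimated correlation), with the triglyceride-forming enzyme Dgat1 at -1.32. Hnf4g was at -1.30. Of 18 Paneth cell genes 9 were lower and 3 higher (11 and 3 over the list alone; camera adjusted p = 0.0108, against adjusted p = 0.46 with an estimated correlation), a call that was lost without Sublow replicate B or Negative replicate C (up to adjusted p = 0.0714). The lipase Pnliprp2 was at -2.45, and the defensins Defa31 at -4.15 and Defa30 at -3.53. Mptx2 (-3.09), Defa23 (-3.74) and Defa3 (-2.98) were lower by rule too. Higher by rule were the interferon-inducible GTPase Gvin1 (5.84, but 2.56 with edgeR and 2.57 with DESeq2), Gip, the urea cycle enzyme Ass1 (4.29, but 2.51 with edgeR and 2.58 with DESeq2), Cd177 (3.96) and the phosphodiesterase Pde2a (3.96). From summed reads the folds were 5.20 for Gvin1 (57.1 on the log2 scale), 8.51 for Gip (24.9) and 5.48 for Ass1 (19.6), and the log2 difference of Gip was 2.91 without Negative replicate B and 6.09 without A. Without single libraries the adjusted p rose to 0.0946 for Gvin1 (Negative B, and above the threshold without Sublow A or C or Negative C) and to 0.0561 for Ass1 and 0.0501 for Defa30 (both Negative B). It rose to 0.122 for Mptx2 (Sublow C, also Negative B or C), to 0.107 for Defa3 (Negative B, also Low A, any Sublow library or Negative C) and to 0.127 for Defa23 (Negative B, also every other Low, Sublow or Negative library).

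By limma with Benjamini-Hochberg adjustment, 4597 genes differed between Sublow and Negative, 2500 higher and 2097 lower in Sublow (6030 with the replicate letter as a block). At 2-fold or more, 1679 were higher and 663 lower, and 6594 genes (39.8%) had no overlap between the 3 libraries of either population, where chance gives 10%. The count fell to 46 (41 higher and 5 lower) in a fit of these 6 libraries alone and was 6939 with library weights, 1729 without Negative replicate B (1404 higher and 325 lower), 2763 without Sublow replicate A (1824 and 939) and 2186 without Sublow replicate C (1469 and 717). With the deposited scaling 54.4% of called genes were higher in Sublow, against 86.3% when scaled to the same total (median gene at 0.23), 64.6% with quantile scaling, 67.2% with edgeR and 48.1% with library weights. It was 81.2% without Negative replicate B, 66.0% without Sublow replicate A and 67.2% without Sublow replicate C.

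The comparison of Sox9 High with Sox9 Sublow set enteroendocrine and tuft cell genes against goblet, cell cycle and enterocyte genes. Siglecf measured 9276 ± 361 in High and 6.48 ± 2.71 in Sublow (log2 difference 10.35 ± 0.67 (SE), adjusted p = 1.71e-07). Muc2 measured 1702 ± 353 against 141009 ± 29689 (log2 difference -6.37 ± 0.38 (SE), adjusted p = 9.02e-08). All 26 tuft cell genes (camera adjusted p = 1.37e-18, against adjusted p = 0.161 with an estimated correlation) and all 18 granule genes (camera adjusted p = 1.7e-13, against adjusted p = 0.0902 with an estimated correlation) were higher in High, also over each list alone. Afp (10.86), Nts (10.59) and Pyy (10.09) were also among the largest rises by rule. From summed reads Afp was 738-fold higher (95% counting interval 487 to 1178), against 1856-fold on the log2 scale, and Nts 554-fold, against 1541-fold. All 22 Afp reads in Sublow came from a single library, and the counting interval does not cover that spread between libraries. Goblet cell genes were lower in High in 18 of 19 cases, also over the list alone (camera adjusted p = 1.33e-10, against adjusted p = 0.3 with an estimated correlation), with Zg16 at -6.93 and Clca1 at -6.37. Ido1 (-6.30) and Fer1l6 (-6.16) fell with them. All 24 mitotic genes (camera adjusted p = 8.26e-12, against adjusted p = 0.409 with an estimated correlation) were lower, and 18 of 21 brush border enzymes and transporters were lower and 1 higher (camera adjusted p = 1.33e-06, against adjusted p = 0.587 with an estimated correlation), with the same counts over each list alone. Active stem cell genes went both ways, 5 of 24 higher and 7 lower, also over the list alone (camera adjusted p = 0.467). Lgr5 (1.57) and Msi1 (3.23) were higher in High, and Slc12a2 (-2.06) and Cdk6 (-1.93) lower. Limma called 8622 genes, 4421 higher and 4201 lower in High (9373 with the replicate letter as a block), and 9721 genes (58.6%) had no overlap between the 3 libraries of either population, where chance gives 10%. At 2-fold or more, 3092 were higher and 2548 lower. Scaling to the same total moved the median gene to 0.22 and 63.2% of called genes were then higher, against 51.3%.

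Genes higher in a single population than in each of the other 3 numbered 2582 in High, 182 in Low, 10 in Sublow and 1547 in Negative, of which 1799, 72, 2 and 496 were at least 2-fold above every other population. High was led by Sbpl, with a smallest log2 difference of 8.28, then Prkcb (6.31), Afp (6.12), Siglecf (5.96) and Basp1 (5.93). Low was led by the receptor Tnfrsf19 (3.32), the peroxidasin Pxdn (2.27), the glutamate transporter Slc1a2 (2.15), the RNA-binding protein Mex3a (1.75) and Lgr5 (1.68). In Sublow the sulfotransferase Chst4 (1.10), the peptide guanylin (Guca2a, 1.09), Spats2l (0.91), the potassium channel Kcnk6 (0.79) and the cell cycle factor E2f2 (0.68) came first. Negative was led by Cyp2b10 (2.32), Defa30 (2.27), apolipoprotein C3 (Apoc3, 2.20), Unc93a2 (2.18) and Defa31 (2.10). The counts of the last 3 populations depended on the processing and on single libraries. Low had 372 genes with the replicate block, 503 scaled to the same total, 403 with quantile scaling and 1084 with library weights. Sublow had 17, 1, 8 and 51 in the same order, and 23 with DESeq2, while Negative had 458 scaled to the same total, 759 with quantile scaling and 1013 with edgeR. Low had 60 genes without Low replicate A, 90 without Low B, 75 without Low C, 94 without Sublow A, 61 without Sublow B and 788 without Sublow C. Sublow had between 1 gene (without Low replicate C) and 30 (without Low replicate B), with 2 without Low A or Sublow C and 6 without High A. Negative had 248 without Negative replicate B, 976 without Negative C, 688 without Sublow A, 590 without Sublow C and 2087 without Sublow B. A fit of the 6 Sublow and Negative libraries alone called 5 genes lower and 41 higher in Sublow. Enrichment in Negative needs a call above Sublow, so nearly all of the 1547 genes depend on the fit of all 12 libraries.

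**Figure D4:**
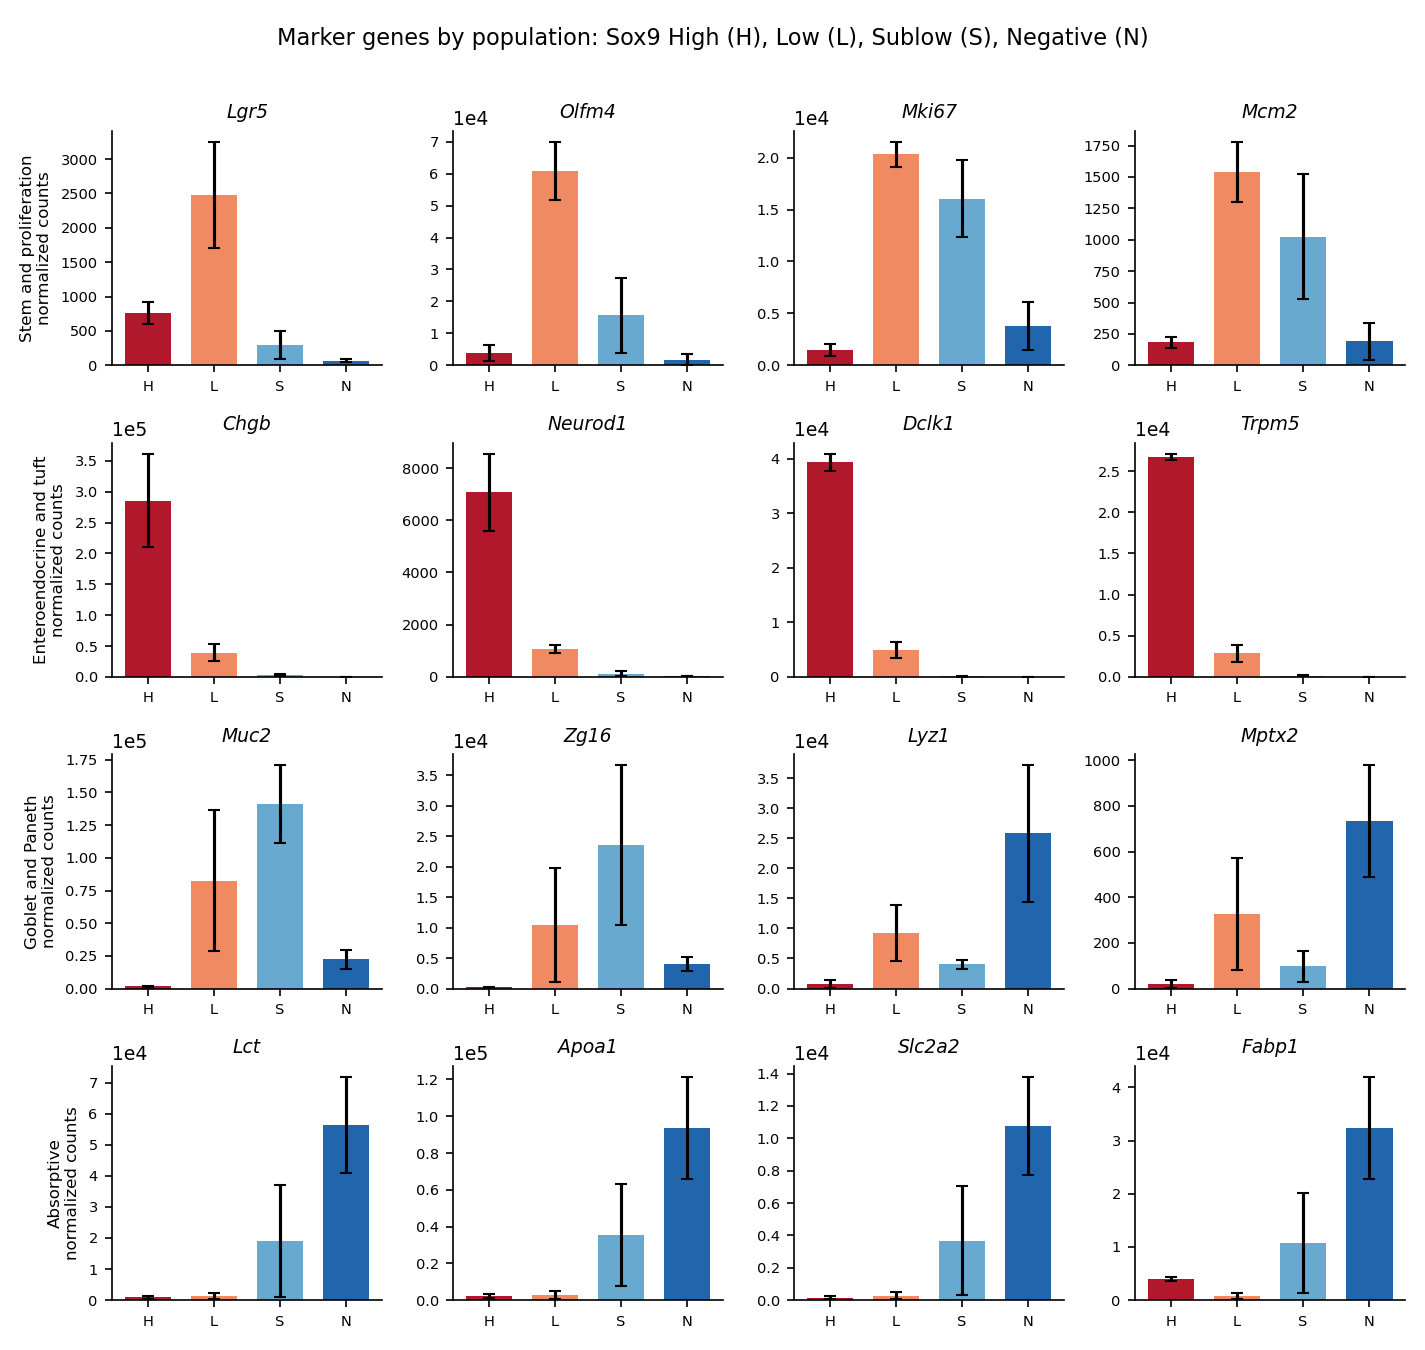
Normalised counts (y axes, mean and SD, n = 3) of marker genes in High (H), Low (L), Sublow (S) and Negative (N), each panel on its own linear axis from 0. Dclk1 is highest in High (39366 ± 1548), Lgr5 in Low (2476 ± 769), Muc2 in Sublow (141009 ± 29689) and Lct in Negative (56355 ± 15412). Muc2 was not called between Sublow and Low (82498 ± 53807 in Low, limma adjusted p = 0.0974).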

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

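Sox9 and the 217 pairs of a named gene and a comparison that were followed kept their direction in each alternative that gave a value. Sox9 passed in each of these. Some genes named with values only, such as Ptprc, Trpm5 and Mki67 in High against Low, were not followed. Named genes were mostly picked as called, and list members mostly because their call held in every alternative, so this stability was largely set by the choice. Il25 and Wif1 were not tested at a mean of at least 50, and the fits of 6 libraries alone were counted only, not read gene by gene. With the 2-fold minimum set aside, counts of called genes for High against Low (6248 to 9327), Negative against Low (8374 to 10495), High against Negative (7565 to 10012), High against Sublow (7273 to 11077), any difference among the 4 populations (9798 to 13390) and genes enriched in High (2024 to 3156) stayed within 1.5 times the reported counts. Without single libraries they ran from 5938 to 7971, 8305 to 9987, 8146 to 9691, 7545 to 8655, 10704 to 11928 and 2145 to 2742. A fit without the Sublow libraries, chosen after the data were seen, called 8037 for High against Low, 9973 for Negative against Low and 9665 for High against Negative. The cause of the changes below was not tested unless stated.

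A 2-fold minimum, by construction stricter, left 4382 genes for High against Low, 2176 for Sublow against Low, 6130 for Negative against Low, 2342 for Sublow against Negative and 5640 for High against Sublow, and 72, 2 and 496 enriched in Low, Sublow and Negative. Library weights, which gave Sublow A 5.71, B 0.418 and C 0.215, called 7880 for Sublow against Low and 6939 for Sublow against Negative, with 1084 enriched in Low and 51 in Sublow. Fits of the 6 libraries compared called fewer genes where Sublow took part (2473 for Sublow against Low, 46 for Sublow against Negative, 7692 for High against Sublow) and more elsewhere (8525 for High against Low, 9563 for Negative against Low, 9376 for High against Negative). With the replicate block, 372 genes were enriched in Low and 17 in Sublow. Scaling to the same total gave 503 enriched in Low, 1 in Sublow and 458 in Negative, quantile scaling 403 in Low and 759 in Negative, edgeR 1013 in Negative and DESeq2 23 in Sublow. Without single libraries, Sublow against Low ran from 2500 to 5603 and Sublow against Negative from 1729 to 6239, and genes enriched in Low from 60 to 788, in Sublow from 1 to 30 and in Negative from 248 to 2087.

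Of 228 gene list tests 123 were called, and 0 with an estimated correlation. With the replicate block 10 further tests were called and 0 lost, and the villus tip list was among those gained in Negative against Low (adjusted p = 0.0206). Quantile scaling gained 13, lost 11 and reversed 1, scaling to the same total gained 15 and lost 5, library weights gained 9 and lost 6, no filter gained 14 and lost 0, a mean of at least 50 gained 4 and lost 3, edgeR gained 2 and lost 2, DESeq2 gained 2 and lost 4, a pseudocount of 0.5 gained 1 and robust empirical Bayes lost 1. With fry, which does not compare a list with other genes, 36 were gained and 8 lost. Leaving out single libraries gained 0 to 7 and lost 0 to 3. The pan-epithelial list, not called between Sublow and Negative (adjusted p = 0.888), was higher in Sublow with quantile scaling (median 0.42, adjusted p = 0.0206), the opposite of its reported direction. The S phase list of Sublow against Low was not called when scaled to the same total (adjusted p = 0.123), with edgeR (0.146) or with DESeq2 (0.201), nor the Paneth list when scaled to the same total (0.104). Gvin1, called higher in Sublow than in Negative, had an adjusted p of 0.16 with edgeR and 0.226 with DESeq2, the highest of its alternatives. In the same comparison the call of Ass1 was lost with DESeq2 (0.0802), that of Mptx2 with library weights (0.0999), scaling to the same total (0.0502) and quantile scaling (0.0508), and that of Defa3 with a pseudocount of 0.5 (0.0678) and scaling to the same total (0.0608). Defa23 lost its call with a pseudocount of 0.5 (0.0723), no filter (0.0593), robust empirical Bayes (0.0692), scaling to the same total (0.0665) and quantile scaling (0.0597). Guca2a, higher in Sublow than in Low, lost it with scaling to the same total (0.067) and quantile scaling (0.055), and Neurog3, lower in High than in Low, with a pseudocount of 0.5 (0.0679), no filter (0.0546) and robust empirical Bayes (0.0515). Depth limits what could be seen of genes with few reads: 3 counts are 2.38 to 4.61 normalised units. Genes without a value of at least 10 in at least 3 of the 12 libraries were not tested.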

Other observations

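Genes of the protein and energy machinery differed between the populations as well. Of 85 cytosolic ribosomal proteins 72 fell in High against Low (77 adjusted over the list alone; median -1.40, camera adjusted p = 5.13e-19, against adjusted p = 0.381 with an estimated correlation) and 58 fell and 3 rose in Negative against Low (61 and 3 adjusted over the list alone; camera adjusted p = 4.66e-06, against adjusted p = 0.586 with an estimated correlation). Of 82 nuclear genes of oxidative phosphorylation 65 rose in Sublow (70 over the list alone; median 0.72, camera adjusted p = 2.46e-25, against adjusted p = 0.156 with an estimated correlation) and 76 in Negative, also over the list alone (median 1.23, camera adjusted p = 1.97e-20, against adjusted p = 0.285 with an estimated correlation), while 43 fell and 1 rose in High (46 and 1 over the list alone; camera adjusted p = 2.74e-09, against adjusted p = 0.381 with an estimated correlation). All 13 mitochondrially encoded genes rose in Negative, also over the list alone (camera adjusted p = 2.17e-05, against adjusted p = 0.338 with an estimated correlation; adjusted p = 0.346 with quantile scaling). Antigen presentation genes rose in 4 of 10 cases in Negative, also over the list alone (camera adjusted p = 0.0206, against adjusted p = 0.512 with an estimated correlation), and in High 5 fell and 2 rose (5 and 3 over the list alone; camera adjusted p = 0.381), Cd74, the invariant chain, at -2.28 and H2-D1 at 2.12. Of 18 Polycomb and DNA methylation genes 8 fell and 4 rose in High (9 and 4 over the list alone; camera adjusted p = 0.263), with the methyltransferase cofactor Uhrf1 at -4.17 and Dnmt3a at 0.90, and 12 fell and 3 rose in Negative, also over the list alone (camera adjusted p = 0.0142, against adjusted p = 0.338 with an estimated correlation). Chromatin remodelers and histone modifiers rose in 9 and fell in 5 of 26 cases in High (10 and 5 over the list alone; camera adjusted p = 0.754). Across 6130 genes at least 2-fold apart between Low and Negative, Sublow lay at a median of 0.506 of the way from Low to Negative (quartiles 0.334 and 0.623), with 93.4% of genes between both. This position is that of the mean of the Sublow libraries, which differed widely, and does not place each of them.

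Of the remaining lists, reserve stem cell genes fell in 5 of 7 cases in Negative against Low, also over the list alone (camera adjusted p = 0.00916, against adjusted p = 0.338 with an estimated correlation). Villus tip genes rose in 6 and fell in 2 of 10 cases (7 and 2 over the list alone; camera adjusted p = 0.0818, and 0.0206 with the replicate letter as a block). Pan-epithelial genes rose in 5 and fell in 2 of 8 cases, also over the list alone (camera adjusted p = 0.108). Dissociation and stress genes had no called member in Sublow against Low, also over the list alone (16 measured, camera adjusted p = 0.794). Of the lists of other cells, whose summed levels were not all alike (endothelial genes 1648 ± 161 in High and 1316 ± 79.5 in Low), camera gave an adjusted p in High against Low of 0.591 for stromal and muscle, 0.677 for endothelial, 0.171 for neuron and glia, 0.677 for erythrocyte and 0.931 for B and plasma cell genes (1 gene measured).

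The explanations weighed here for 3 patterns were chosen, with their tests, after the results were seen. Ptprc, a phosphatase of leukocytes, measured 2469 ± 779 in High and 89.2 ± 26.8 in Low, and leukocytes in the High libraries might be the cause. From Low to High, 35 other T cell, B cell and myeloid genes together went from 955 ± 56.9 to 1002 ± 178, an increase that was 0.0198 (spread 0.0455) of that of Ptprc. A set of 12 genes of most leukocytes went from 86.7 ± 3.61 to 125.1 ± 24.0, a ratio of 0.0161 (spread 0.00664). Both ratios were far below the 1 that leukocytes would give, so leukocytes expressing these sets do not account for most of the rise of Ptprc. Genes outside both sets were not part of this test. Among them, Rac2 rose from 71.3 ± 31.2 in Low to 3490 ± 398 in High, and Plek from 27.1 ± 2.24 to 1436 ± 423. The design gives no biological explanation to test, and none was tested.

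Paneth cell genes were higher in Negative than in Sublow, which reads shared among near-identical Defa genes could produce within the family. The summed family of 35 Defa genes had a log2 ratio of 2.42 (SE 0.508), and 5 of the 9 list members that fell were not Defa genes: Lyz1, Mptx2, Habp2, Pnliprp2 and Sntb1. RNA of broken Paneth cells, carried into every sort, could add to all populations. The summed list differed 15.1-fold (spread 5.34) between Negative and High, but this ratio restates the pattern itself, so how much such RNA adds is left open. Whether Paneth cells fell into the Negative gate was not tested, and no biological explanation was tested.

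Enteroendocrine and tuft cell genes were present in Low, where a fixed share of High cells sorted into that gate could place them. At a fixed share all members would have the same ratio, but 6 of 26 tuft genes lay more than 3 standard errors from the median log2 difference of 3.10 (Low at 11.6% of High), as did 3 of 18 granule genes (median 2.83, 14.1%). Neurog3 was lower in High (log2 difference -3.09, SE 1.11), where such a share as the only source predicts a rise. Its limma call was lost without some single libraries (adjusted p up to 0.127). Cells of Low may express Neurog3 themselves, so its level cannot show where the other genes in Low come from. By the members that lay off the median, a fixed share does not account for all of these genes, although part of their level in Low may come from it. No biological explanation was tested.

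Other splits of the same libraries into groups of 3 were tried after the results were seen. Between pairs of populations only 10 splits exist, too few for a share under 0.05. Other splits and groupings put libraries of differing populations together, which widens the spread within groups. Low counts of called genes in them were thus largely set in advance, and do not show how many of the real calls are false. The real split was the 1 of 10 with the most calls in each: 7110 for High against Low, 3979 for Sublow against Low, 9474 for Negative against Low and 9054 for High against Negative (highest other 1 in each), 4597 for Sublow against Negative (highest other 2) and 8622 for High against Sublow (highest other 0). For any difference among the 4 populations, 1 of 100 groupings reached 11521 genes, the real one, and the highest other gave 2691 and kept the Negative libraries together. For genes enriched in High the real grouping was 1 of 100 (highest other 1693, which kept the High libraries together), and for those enriched in Low, Sublow and Negative that other grouping also reached the real count, making 2 of 100 each. For gene list tests, 2 of 100 groupings gave as many as the 123 calls of the real one. The highest other gave 124 and the median of the others was 93, so the number of called lists at the fixed correlation says little about the grouping.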
